A study of Mus musculus with 8 samples.

How the data were processed

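The series holds RNA sequencing of mouse brain in 8 libraries, per the labels from wild-type animals, in 4 groups of 2 given by fraction (Total or IP) and stress (control or foot shock). Per the labels' protocols, RNA was purified with the RNeasy Mini Kit, checked on a Fragment Analyzer, amplified with the Ovation RNA Amplification System V2 and sequenced on a HiSeq instrument. Per the submitters' processing notes, FastQC, HTSeq and the mm10 build were used. The aligner, the annotation release, the counting and strand settings and any pooling of libraries are not given in the sources used here. The labels do not say whether a replicate is 1 animal or a pool.

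The deposited per-sample files hold raw read counts per Ensembl gene, which the authors made with HTSeq, per the submitters' processing notes. They list 55536 genes and end with summary lines that name no gene. Of the genes, 55479 took their symbol from the authors' series table and 57 from the reference table of gene names, and 0 were left without one. The deposited series table repeats these counts, and all 55535 genes it lists held equal counts in every library. Gene start and end positions came from the same deposited table, whose header gives no build, and are taken as mm10 from the submitters' processing notes. The authors' deposited tables of Total against IP give a log2 fold change of Total over IP and a mean log2 CPM, per the file headers. They also give a p-value and a false discovery rate per gene, per the file headers, and the test behind them is not stated. The deposited RPKM and TPM columns repeat the counts after division by gene span and were not used. Reads the counting step assigned to no gene (16.2% to 20.6% of the total in each library) or to several (11.8% to 16.0%) stayed out of library sizes and tests.

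Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by filterByExpr, which left 19782, and libraries were scaled by TMM (factors 0.9374 to 1.042). A quasi-likelihood model with robust moderation and a mean for each group was fitted to all 8 libraries, with 4 residual degrees of freedom and a median of 5.13 prior degrees of freedom. Its common biological coefficient of variation was 0.664. Tests were made in 5 comparisons, IP against Total in control, IP against Total after shock, shock against control in Total, shock against control in IP, and the difference between the last 2. The p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. With libraries of 18054492 to 29016005 reads on genes the median SE of a log2 change was 0.713 to 0.719, and 1.01 for the difference, so small changes in single genes would be missed.

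The comparisons, the tests, the alternatives, the rule for naming genes and 35 gene lists were written down before the data were examined. The rule names fixed genes of the stress response and cell types in every comparison, the 6 passing genes with the largest change in each direction, and the 4 members of smallest p in each list described. The passing genes needed a mean log2 CPM of at least 3, an established symbol and both libraries of a group above both of the other, and where fewer than 6 passed, up to 3 not passing were added in order of p. Lists with at least 5 tested members were tested with camera on voom values with the correlation between genes preset at 0.01, adjusted over the 35 lists, and again with an estimated correlation. Members were counted as passing over all genes and adjusted over the list alone. Some genes, such as Per1, Gabra1 and Slc17a6, belong to several lists, so the list results are not independent of each other. The lists cover markers of the lateral and medial habenula, thalamus, hippocampus, choroid plexus and ependyma, astrocytes, oligodendrocytes, OPC, microglia, endothelial and mural cells, erythrocytes and neurons. They also cover glutamatergic and GABAergic neuron genes, potassium, sodium, calcium and HCN channels, transmitter receptors, synaptic vesicle and postsynaptic genes, neuropeptides, activity-induced, glucocorticoid-induced, heat shock and chaperone genes. The rest are ribosomal proteins, translation factors, the mTOR and S6 kinase pathway, mitochondrially encoded and nuclear-encoded respiratory genes, noncoding RNAs and histones.

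The scripts were tested on simulated counts for 19782 genes with 100 genes changed 2-fold and 100 changed 8-fold. The changed genes were drawn only from those at a mean of at least 8 CPM, so recovery at lower counts was not measured. For IP against Total in control 12% and 78% of them were recovered with 5 false calls, for shock against control in IP 10% and 79% with 10 false calls, and for the difference 4% and 68% with 8 false calls. With no change simulated there were 0 calls. For IP against Total in control, a list shifted on purpose was called by camera with the preset correlation (adjusted p = 2e-19, and 0 of 34 unchanged lists) and missed with an estimated correlation (0.073). Simulated genes were drawn independently, so this could not show false list calls from genes that vary together. Alternatives changed the scaling (RLE, upper quartile, library totals), the filter (none, or at least 5 CPM in 2 libraries), the test (DESeq2, voom), the use of a block or of 4 libraries only, and left out each library in turn. A likelihood-ratio test and fits without mitochondrially encoded genes or choroid plexus and ependymal markers were added after the data were seen. A genome sequence was not used here, so reads shared between mitochondrial genes and their nuclear copies, or between globin copies, could not be reassigned.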

Results

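RNA was sequenced from mouse brain, placed by the series description in the lateral habenula, a small nucleus above the thalamus that carries signals of aversion to midbrain neurons. The labels set control samples against samples taken after acute foot shock stress. In each state, libraries were made from the whole RNA of the sample (Total) and from mRNA recovered with phosphorylated ribosomes (IP), a capture meant to favour what recently active cells were translating. The 8 libraries formed 4 groups of 2, namely Total control, IP control, Total shock and IP shock. Reads on genes numbered 26176621 and 18054492 in the Total control libraries, 23300886 and 21893739 in IP control, 20034542 and 23326396 in Total shock, and 22664759 and 29016005 in IP shock. Between 21428 and 23663 genes had at least 1 read in a library. Group values below are CPM (reads of a gene relative to its library, scaled by TMM) as mean ± SD with n = 2, and log2 fold changes are given ± SE from a fit of all 8 libraries. Gene calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19782 genes, and list calls on limma's camera. The labels do not say whether the replicates were separate animals or pools, so every p-value measures the spread between these libraries only. An exact test of 2 against 2 libraries cannot reach 0.05, so every call leans on spread pooled across groups and genes.

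Libraries of the same group were not close to one another. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.902 in Total control, 0.895 in IP control, 0.910 in Total shock and 0.898 in IP shock. The mean was 0.901 within groups, 0.892 between stress states of the same fraction and 0.881 between fractions. The variance between replicates, as chi-square per degree of freedom, was 47.1 to 95.1 times what counting error alone would give. Of genes at a mean of at least 5 CPM, 2.32% to 4.33% lay at least 4-fold apart. Reads from the mitochondrial genome took 3.71% and 3.13% of reads on genes in the Total control libraries and 0.256% and 0.265% in IP control. They took 11.7% and 11.1% in Total shock and 1.51% and 1.1% in IP shock. Choroid plexus and ependymal markers took 0.435% and 0.220% of reads on tested genes in Total control, 3.69% and 1.92% in IP control, 0.15% and 0.169% in Total shock, and 0.650% and 0.974% in IP shock. The 95% Wilson intervals of all these shares reached at most 0.015 percentage points to either side and cover counting error only.

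The first question was which RNAs the capture favoured in control tissue. Among the genes the naming rule admits, those with the largest increase were Ddx46, Puf60, Snrnp70, Esf1, Map1a and Thrap3, and those with the largest decrease were the mitochondrial ribosomal RNAs. Ddx46, a helicase of the spliceosome, was 4.23 ± 0.26 higher in IP on the log2 scale, with an adjusted p of 1.8e-04. Puf60, a splicing factor (chromosome 15, 76070182 to 76080924, mm10), went from 84.2 ± 8.75 CPM in Total to 1330 ± 61.5 CPM in IP, a log2 difference of 3.98 ± 0.16 (adjusted p = 1.3e-05). Map1a, which binds microtubules in neurons (chromosome 2, 121289600 to 121310832), went from 656 ± 7.96 to 8730 ± 750 CPM, a log2 difference of 3.73 ± 0.21. The other large increases were Snrnp70, a spliceosomal protein, at 3.76 ± 0.29, Esf1, which acts in ribosomal RNA processing, at 3.76 ± 0.19, and Thrap3, an arginine- and serine-rich splicing regulator, at 3.65 ± 0.27. Lowest in IP were the mitochondrial ribosomal RNAs mt-Rnr2 (-4.14 ± 0.18) and mt-Rnr1 (-3.17 ± 0.13). They were followed by Nkain1, which binds the sodium pump (-2.80 ± 0.44), Elovl5, a fatty acid elongase (-2.75 ± 0.44), and the membrane proteins Cmtm5 (-2.55 ± 0.41) and Cldnd1 (-2.54 ± 0.43). Gpr151, a receptor typical of habenula neurons (chromosome 18, 42577881 to 42579652), was lower in IP at 4.14 ± 0.257 against 23.1 ± 1.77 CPM (log2 -2.48 ± 0.38, adjusted p = 0.021), and so was Gfap, the astrocyte filament protein (-2.25 ± 0.42, adjusted p = 0.045). In all, 112 genes were higher and 88 lower. Without 1 library the counts were 24 and 15 (Total control 1), 19 and 12 (Total control 2), 32 and 12 (IP control 1), 47 and 19 (IP control 2), 66 and 34 (Total shock 1), 66 and 35 (Total shock 2), 164 and 131 (IP shock 1), and 164 and 124 (IP shock 2). Ddx46, Puf60, Map1a, Snrnp70, Esf1, Thrap3, mt-Rnr2 and mt-Rnr1 passed without any 1 library, whereas Nkain1, Elovl5, Cmtm5, Cldnd1, Gpr151 and Gfap no longer passed without any 1 library of Total control, IP control or Total shock (adjusted p 0.059 to 0.26).

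Of the 10 fixed genes, Gpr151 and Gfap passed over all genes in control tissue and the other 8 did not. Kcnb1, the delayed rectifier potassium channel named in the series title (chromosome 2, 167095969 to 167190155), stood at 225 ± 0.138 CPM in Total and 191 ± 22.1 CPM in IP (log2 -0.24 ± 0.19, adjusted p = 0.61). Log2 values of IP over Total were 1.66 ± 0.44 for Fos (adjusted p = 0.13), 1.15 ± 0.26 for Egr1 (0.082), 0.74 ± 0.58 for Arc (0.60) and 2.55 ± 1.4 for Npas4 (0.44), which are transcription factors or synaptic genes induced by neuronal activity. They were -0.56 ± 0.22 for Rps6, whose protein carries the phosphate used for capture (adjusted p = 0.29), -0.62 ± 0.15 for Mbp, a myelin protein (0.092), and -0.66 ± 0.20 for Slc17a6, the vesicular glutamate transporter of habenula neurons (0.19).

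Of the 35 lists fixed before the data were examined, 8 were higher and 5 lower in IP of control tissue with camera's preset correlation of 0.01. With an estimated correlation 0 of the 35 passed, and the adjusted p of each list with it is given in parentheses after "estimated". Astrocyte and oligodendrocyte markers were lower, whereas microglia markers (median 0.34, adjusted p = 0.79) and OPC markers (median -0.37, 0.72) were not called. Of 21 tested oligodendrocyte markers, 6 fell over all genes and 14 adjusted over the list alone (median log2 -1.08, adjusted p = 4.9e-13, estimated adjusted p = 0.15), among them Plp1, the main myelin proteolipid (-1.32 ± 0.13), Mal (-1.75 ± 0.25) and Ermn (-2.39 ± 0.35). Of 20 astrocyte markers, 4 fell over all genes and 9 adjusted over the list alone (median -1.22, adjusted p = 2.4e-07, estimated adjusted p = 0.13), including the glycolytic enzyme Aldoc (-1.40 ± 0.17) and the water channel Aqp4 (-1.44 ± 0.20). Of 11 mitochondrially encoded mRNAs, 7 fell over all genes and 9 adjusted over the list alone (median -2.18, adjusted p = 3.5e-10, estimated adjusted p = 0.29), with mt-Co1, a cytochrome oxidase subunit, at -2.41 ± 0.16. Nuclear-encoded oxidative phosphorylation genes went the other way. All 76 had positive values, 7 rose over all genes and 43 adjusted over the list alone (median 0.76, adjusted p = 6.1e-30, estimated adjusted p = 0.29), such as the ATP synthase subunit Atp5b (1.09 ± 0.12) and the cytochrome oxidase subunit Cox6a1 (1.31 ± 0.15). Of 86 cytosolic ribosomal proteins, 4 fell over all genes and 9 adjusted over the list alone (median -0.33, adjusted p = 6.5e-08, estimated adjusted p = 0.67), with Rps27 at -1.23 ± 0.17 and Rpl41 at -1.21 ± 0.20. Without 1 library these calls held, but those of named members did not all hold. Aldoc no longer passed without IP control 1, IP control 2 or Total control 2 (adjusted p 0.051 to 0.080), Mal, Ermn, Aqp4 and Rps27 without any 1 control library (0.059 to 0.14), Rpl41 without any 1 control or Total shock library (0.053 to 0.21), Atp5b without Total control 1, Total control 2 or IP control 1 (0.051 to 0.076), and Cox6a1 without either Total control library (0.070).

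Choroid plexus, thalamus and erythrocyte lists were higher in the IP of control tissue, whereas lateral habenula markers (median -0.05, adjusted p = 0.72), neuronal markers (median -0.02, 0.89) and hippocampus markers (median 0.29, 0.37) were not called. Over all genes 2 of 18 lateral habenula markers rose and 1 fell, and 1 of 21 neuronal markers rose and 1 fell. Ttr, the thyroid hormone carrier made by choroid plexus (chromosome 18, 20665280 to 20674321), stood at 2459 ± 1198 CPM in Total and 25530 ± 12230 CPM in IP (log2 3.38 ± 0.41, adjusted p = 0.0067). Of 18 choroid plexus and ependymal markers, 4 rose over all genes, while 10 rose and 1 fell adjusted over the list alone (median 1.60, adjusted p = 4e-06, estimated adjusted p = 0.29). They included Clic6 (2.72 ± 0.41) and Kcne2 (3.28 ± 0.54). Of 18 thalamus markers, 2 rose over all genes, the kinase Prkcd (1.38 ± 0.16) and the troponin Tnnt1 (1.59 ± 0.26), and 10 rose and 1 fell adjusted over the list alone (median 0.60, adjusted p = 2.4e-06, estimated adjusted p = 0.23). Of 5 erythrocyte genes, 1 rose over all genes, the globin Hbb-bs (2.44 ± 0.40), and 4 adjusted over the list alone (median 2.44, adjusted p = 2.1e-04, estimated adjusted p = 0.23). The globin copies share reads, so their separate values are uncertain. Ttr lost its call without Total control 2 (adjusted p = 0.057), Prkcd without either Total control library (0.069 and 0.076), Clic6 without Total control 1, Total control 2 or IP control 1 (0.065 to 0.15), Hbb-bs without any 1 control library (0.054 to 0.23), and Kcne2 and Tnnt1 without any 1 control or Total shock library (0.054 to 0.21).

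Activity-induced genes, postsynaptic scaffold genes, nuclear-retained noncoding RNAs, medial habenula markers and heat shock genes were the remaining lists called in the IP of control tissue. Of 39 activity-induced genes, 3 rose and 1 fell adjusted over the list alone (median 0.70, adjusted p = 0.0095, estimated adjusted p = 0.29). Those that rose were the synaptic scaffold Homer1 (1.21 ± 0.25), Egr1 and Fos, and the pseudokinase Trib1 fell (-1.34 ± 0.34). Over all genes 0 of them passed edgeR's test, although 6 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 5 higher and 1 lower, and voom called 0. Of 28 postsynaptic scaffold genes, 1 rose over all genes, Dlgap1 (1.09 ± 0.21), and 5 adjusted over the list alone (median 0.29, adjusted p = 0.0017, estimated adjusted p = 0.42). Of 13 nuclear-retained noncoding RNAs, 2 rose over all genes, Snhg14 (1.04 ± 0.18) and Rian (0.76 ± 0.14), while 3 rose and 1 fell adjusted over the list alone (median 0.33, adjusted p = 0.0095, estimated adjusted p = 0.23). Among 23 medial habenula markers 3 fell adjusted over the list alone, such as the calcium-binding protein Calb2 (-1.23 ± 0.24). Their median was -0.41 (adjusted p = 0.0095, estimated adjusted p = 0.23). Over all genes 0 of them passed with edgeR, against 6 lower at an unadjusted p under 0.05, 3 lower with DESeq2 and 0 with voom. Of 14 heat shock genes, 1 fell adjusted over the list alone, the small chaperone Cryab (-1.08 ± 0.23), while the list's median was 0.35 and its call was higher (adjusted p = 0.0095, estimated adjusted p = 0.36). In that list 0 genes passed over all genes with edgeR, against 3 higher and 1 lower at an unadjusted p under 0.05, 1 lower with DESeq2 and 0 with voom. The heat shock call ended without Total control 1 (adjusted p = 0.12) or IP control 2 (0.097), that of the nuclear-retained RNAs without IP control 1 (0.14), that of the medial habenula markers without Total control 2 (0.067), and that of the activity-induced genes without IP control 2 (0.061). Dlgap1, Snhg14 and Rian lost their calls without any 1 control or Total shock library (0.063 to 0.31).

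The same comparison after shock asked which RNAs the capture favoured in stressed tissue. Among the 6 highest genes the naming rule admits, 5 were the same as in control tissue, and among the 6 lowest only mt-Rnr2 and mt-Rnr1 were. Ddx46 was 3.98 ± 0.26 higher in IP, Thrap3 3.93 ± 0.28, Puf60 3.87 ± 0.16 (1270 ± 81.1 against 86.8 ± 8.49 CPM, adjusted p = 2.1e-05), Snrnp70 3.57 ± 0.28, Esf1 3.44 ± 0.19 and Rsrc2, an arginine- and serine-rich protein, 3.35 ± 0.20. Lowest were mt-Rnr2 (-3.90 ± 0.18), mt-Rnr1 (-2.86 ± 0.13), the astrocyte receptor Gpr37l1 (-2.42 ± 0.41, adjusted p = 0.043), the myelin protein Mal (-2.10 ± 0.25, 0.0092), the actin-binding Tmsb4x (-1.81 ± 0.19, 0.0049) and mt-Co1 (-1.73 ± 0.15, 0.0012). Kcnb1 stood at 249 ± 9.08 CPM in Total and 317 ± 65.2 CPM in IP (log2 0.35 ± 0.19, adjusted p = 0.51). The values were -1.10 ± 0.36 for Gpr151 (0.29), 0.85 ± 0.43 for Fos (0.48), 0.79 ± 0.25 for Egr1 (0.28), 0.68 ± 0.58 for Arc (0.70), 0.54 ± 1.3 for Npas4 (0.93), -0.79 ± 0.40 for Gfap (0.49), -0.21 ± 0.14 for Mbp (0.62), -0.20 ± 0.20 for Slc17a6 (0.75) and -0.57 ± 0.22 for Rps6 (0.37). In all, 70 genes were higher and 31 lower. Without 1 library the counts were 15 and 6 (Total shock 1), 20 and 7 (Total shock 2), 33 and 20 (IP shock 1), 103 and 33 (IP shock 2), 51 and 15 (Total control 1) and 50 and 15 (Total control 2). The calls of Ddx46, Thrap3, Puf60, Snrnp70, Esf1, Rsrc2, mt-Rnr2, mt-Rnr1 and mt-Co1 held without any 1 library. Gpr37l1 lost its call without any 1 of the 8 (adjusted p 0.055 to 0.40), Mal without either Total shock library (0.055 and 0.10) and Tmsb4x without Total shock 1 (0.062).

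Of the 13 lists called in control tissue, 11 were called in the same direction after shock, and choroid plexus and heat shock genes were not. The heat shock genes had a median of 0.03 (adjusted p = 0.92), with the direction turned without Total shock 1 (1.0) or IP shock 2 (0.42). There 9 lists were higher and 8 lower with the preset correlation, and 0 with an estimated one. Of 21 oligodendrocyte markers, 2 fell over all genes, Mal and Plp1 (-0.94 ± 0.13), and 11 adjusted over the list alone (median -0.94, adjusted p = 8.9e-13, estimated adjusted p = 0.16). Of 20 astrocyte markers, 2 fell over all genes, Gpr37l1 and Aldoc (-1.45 ± 0.17), and 11 adjusted over the list alone (median -1.06, adjusted p = 6.5e-11, estimated adjusted p = 0.061). Of 86 cytosolic ribosomal proteins, 2 fell over all genes, Rps27 (-1.36 ± 0.17) and Rpl41 (-1.28 ± 0.20), and 17 adjusted over the list alone (median -0.44, adjusted p = 1.7e-14, estimated adjusted p = 0.26). Of 11 mitochondrially encoded mRNAs, 1 fell over all genes, mt-Co1, and 7 adjusted over the list alone (median -1.27, adjusted p = 1.8e-13, estimated adjusted p = 0.21). Of 76 nuclear-encoded oxidative phosphorylation genes, 1 rose over all genes, Cox6a1 (1.19 ± 0.15), and 6 adjusted over the list alone (median 0.43, adjusted p = 8.9e-13, estimated adjusted p = 0.32). Of 18 thalamus markers, 2 rose over all genes, Prkcd (1.13 ± 0.16) and Grid2ip (1.76 ± 0.30), and 5 adjusted over the list alone (median 0.42, adjusted p = 2.3e-07, estimated adjusted p = 0.16). Of 5 erythrocyte genes, 1 rose over all genes, Hbb-bs (2.54 ± 0.40), and 4 adjusted over the list alone (median 2.14, adjusted p = 2.2e-04, estimated adjusted p = 0.21). Choroid plexus and ependymal markers had a median of 1.17 but missed the threshold (adjusted p = 0.061). Adjusted over the list alone 10 of them rose and 4 fell, and over all genes 1 rose, Ttr (2.55 ± 0.40, adjusted p = 0.030). The call of the nuclear-encoded oxidative phosphorylation genes ended without IP shock 2 (adjusted p = 0.22). The calls of Aldoc, Cox6a1, Rps27 and Prkcd ended without either Total shock library (0.088 to 0.26), and those of Plp1, Grid2ip, Rpl41 and Hbb-bs without either Total shock library or some of the others (0.054 to 0.38).

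Postsynaptic scaffold genes, glutamate receptors and synaptic vesicle genes were called higher as lists in IP over Total after shock, with 1 member of each passing over all genes. GABA and glycine receptors (median -0.08, adjusted p = 0.37) and monoamine, acetylcholine and opioid receptors (median -0.34, 0.083) were not called. Of 28 postsynaptic scaffold genes, 1 rose over all genes, Dlgap4 (1.01 ± 0.16), while 10 rose and 1 fell adjusted over the list alone (median 0.51, adjusted p = 2.1e-04, estimated adjusted p = 0.26). Of 13 nuclear-retained noncoding RNAs, 2 rose over all genes, Snhg14 (1.45 ± 0.18) and Rian (0.92 ± 0.14), and 4 adjusted over the list alone (median 0.57, adjusted p = 7.1e-04, estimated adjusted p = 0.16). Of 25 glutamate receptors, 1 rose over all genes and over the list alone, the NMDA receptor subunit Grin2b (1.76 ± 0.26), with a median of 0.48 (adjusted p = 0.019, estimated adjusted p = 0.26). Of 33 synaptic vesicle and release genes, 1 rose over all genes, Cplx1 (1.01 ± 0.13), and 3 adjusted over the list alone (median 0.09, adjusted p = 0.042, estimated adjusted p = 0.26). Of 39 activity-induced genes, 3 rose adjusted over the list alone, the clock gene Per1 (1.44 ± 0.27) and the transcription factors Egr3 (1.88 ± 0.41) and Egr2 (8.39 ± 2.1), with a median of 0.50 (adjusted p = 0.0071, estimated adjusted p = 0.24). Egr2 was close to absent from Total, at 0.02234 ± 0.03159 CPM against 9.766 ± 9.657 CPM in IP, so the size of its change is uncertain. The 32 sodium, calcium and HCN channels had a median of 0.31 (adjusted p = 0.025, estimated adjusted p = 0.26). Lists called lower were the medial habenula markers (median -0.45, adjusted p = 0.0015, estimated adjusted p = 0.16), the microglia markers (median -0.76, 0.043, estimated adjusted p = 0.26), the endothelial and mural markers (median -0.87, 0.025, estimated adjusted p = 0.21, with the pericyte gene Rgs5 at -1.18 ± 0.25 passing over the list alone) and the replication-dependent histones (median -0.64, 0.026, estimated adjusted p = 0.26). Over all genes 0 members of the activity-induced, channel, medial habenula, microglia, endothelial and histone lists passed with edgeR or voom. At an unadjusted p under 0.05 there were 9, 2, 1, 0, 2 and 0 members higher and 2, 0, 4, 2, 4 and 1 lower in that order, and DESeq2 called 3, 0, 0, 0, 0 and 0 higher and 0, 0, 2, 0, 2 and 1 lower.

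Several of these calls after shock rested on single libraries. Without Total shock 1, those of the activity-induced genes (adjusted p = 0.14), the sodium, calcium and HCN channels (0.077) and the replication-dependent histones (0.26) ended. Without IP shock 1, those of the activity-induced genes (0.072), the sodium, calcium and HCN channels (0.37), the glutamate receptors (0.23), the synaptic vesicle and release genes (0.28), the endothelial and mural markers (0.081) and the replication-dependent histones (0.081) ended. Without Total shock 2, those of the microglia markers (0.14), the endothelial and mural markers (0.088), the glutamate receptors (0.066) and the synaptic vesicle and release genes (0.053) ended. Without IP shock 2, those of the microglia markers (0.32), the endothelial and mural markers (0.10) and the replication-dependent histones (0.091) ended, and without either Total control library that of the synaptic vesicle and release genes did (0.050 and 0.051). Dlgap4 and Rian lost their calls without any 1 of the 8 libraries (0.052 to 0.33). Grin2b did so without either Total shock library or IP shock 1 (0.12 to 0.25), and Cplx1 and Snhg14 did so without either Total shock library (0.094 to 0.19).

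Calls of IP against Total overlapped between the stress states. The states share no library, but both tests use the same estimate of each gene's spread from all 8 libraries. Calls of the same gene are thus not independent, and the overlap of independent draws is only a rough reference. Of the 112 genes higher in control tissue and the 70 higher after shock, 61 were shared, where independent draws would share 0.396. Of the 88 and 31 lower genes, 22 were shared, against 0.138. Of the genes called in control tissue, 111 of 112 and 88 of 88 had the same sign after shock. Across all genes, which are not independent replicates, the log2 values had Pearson's r = 0.151, and r = 0.667 over the 5690 genes at a mean log2 CPM of at least 5. The authors' deposited tables of Total over IP list 15944 genes. With the sign turned to IP over Total, they call 363 genes higher and 320 lower in control tissue and 226 higher and 156 lower after shock at a false discovery rate of 0.05. All 200 and 101 genes called here were among them. In the authors' deposited table Fos stands at 1.666 in control tissue (false discovery rate 0.0269) and 0.85 after shock (0.468). Gpr151 stands at -2.476 (0.000309) and -1.1 (0.289), and Kcnb1 stands at -0.232 in control tissue (false discovery rate 0.725) and 0.352 after shock (0.608).

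**Figure D1:**
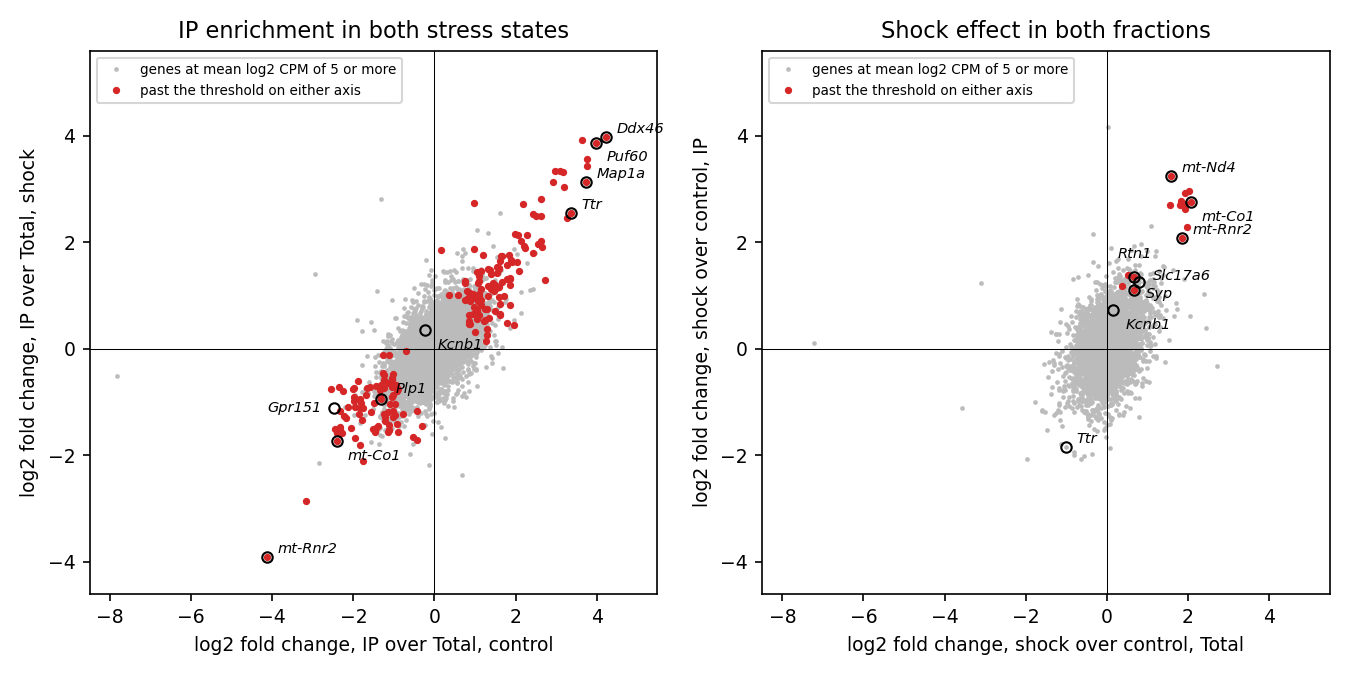
Log2 fold changes of genes at a mean log2 CPM of 5 or more (grey points), with IP over Total in control tissue against the same after shock on the left, and shock over control in Total against the same in IP on the right. Red points passed the test on at least 1 axis and open circles mark named genes; Puf60 lies at 3.98 and 3.87 on the left and mt-Co1 at 2.08 and 2.76 on the right.

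Shock against control in Total RNA asked what stress changed in the whole tissue. Mitochondrial RNAs rose, and no other single gene passed. The cytochrome oxidase mRNA mt-Co1 went from 1270 ± 118 to 5390 ± 22.3 CPM (log2 2.08 ± 0.15, adjusted p = 0.0024). The mitochondrial ribosomal RNAs mt-Rnr1 (1.99 ± 0.13, adjusted p = 0.0012) and mt-Rnr2 (1.85 ± 0.16, 0.0068) rose too. These 3 genes were the only calls higher, and 0 were lower by edgeR. At an unadjusted p under 0.05 there were 769 genes higher and 554 lower, where chance gives 989 in all. DESeq2 called 106 higher and 55 lower, the likelihood-ratio test 47 and 27, and voom 3 and 0. Next in order, without passing, came mt-Nd5 (1.94 ± 0.26, adjusted p = 0.20), mt-Nd2 (1.94 ± 0.28, 0.27) and mt-Nd1 (1.81 ± 0.28, 0.27) among higher genes. Among lower genes came the RNA-binding Rbm47 (-3.09 ± 0.56, 0.38), Fam117a (-3.63 ± 0.71, 0.41) and the retinol carrier Rbp1 (-1.97 ± 0.39, 0.42). Fos was at 7.63 ± 1.03 CPM in control and 27.7 ± 1.78 CPM after shock (log2 1.86 ± 0.44, adjusted p = 0.56). Kcnb1 was at 0.15 ± 0.19 (0.95), Slc17a6 at 0.79 ± 0.20 (0.60), Gpr151 at 0.54 ± 0.36 (0.80), Egr1 at 0.41 ± 0.25 (0.79), Npas4 at 2.60 ± 1.4 (0.76), Gfap at -0.75 ± 0.40 (0.76), Arc at -0.20 ± 0.58 (1.0), Mbp at 0.03 ± 0.14 (1.0) and Rps6 at -0.27 ± 0.22 (0.86). With Total control 1 left out 0 genes passed as higher, with Total control 2 left out 1 did, with either Total shock library left out 2 did, and with either IP shock library left out 7 did. Without Total control 1, mt-Co1 and mt-Rnr1 had an adjusted p of 0.059 and mt-Rnr2 of 0.075. Without Total control 2, mt-Co1 had 0.075 and mt-Rnr2 0.15, and mt-Rnr2 also missed without Total shock 1 (0.10) or Total shock 2 (0.061). The mt-Rnr reads are partly shared with nuclear copies, so the gene they belong to is uncertain.

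Stress hormone targets, inhibitory receptors and chaperones of the secretory pathway were among the lists called higher in Total RNA. With the preset correlation 16 lists were higher and 2 lower, and 0 with an estimated one. Of 11 mitochondrially encoded mRNAs, 1 rose over all genes, mt-Co1, and 8 adjusted over the list alone (median 1.94, adjusted p = 7.3e-25, estimated adjusted p = 0.098). Of 16 glucocorticoid-induced genes, 14 had positive values and 4 rose adjusted over the list alone (median 0.84, adjusted p = 1.4e-07, estimated adjusted p = 0.098). These were the cell cycle inhibitor Cdkn1a (2.46 ± 0.47), the receptor chaperone Fkbp5 (1.89 ± 0.41), the kinase Sgk1 (1.32 ± 0.29) and Per1 (0.85 ± 0.27). Of 20 GABA and glycine receptors, 19 had positive values and 4 rose adjusted over the list alone, Gabra3 (1.38 ± 0.28), Gabra1 (1.21 ± 0.27), Gabbr2 (0.70 ± 0.20) and Glrb (0.83 ± 0.25), with a median of 0.63 (adjusted p = 8.2e-10, estimated adjusted p = 0.098). Of 31 secretory and ER chaperone genes, 29 had positive values (median 0.56, adjusted p = 1e-07, estimated adjusted p = 0.13), with Ssr1 at 0.94 ± 0.22 and Canx at 0.79 ± 0.21, and 0 passed adjusted over the list alone. Of 21 neuronal markers 5 rose adjusted over the list alone (median 0.13, adjusted p = 6.7e-05, estimated adjusted p = 0.10), such as Rtn1, a membrane protein of the neuronal endoplasmic reticulum (0.68 ± 0.13), and the vesicle protein Syp (0.67 ± 0.15). Among the glucocorticoid, GABA and glycine receptor, chaperone and neuronal lists 0 members passed over all genes with edgeR or voom. At an unadjusted p under 0.05 there were 7, 8, 5 and 5 members higher and 1, 0, 0 and 0 lower in that order, and DESeq2 called 3, 2, 1 and 2 higher. The share of mitochondrial reads moved with all of these lists, at 3.71% and 3.13% in control against 11.7% and 11.1% after shock. Housekeeping mRNAs of secreted and membrane proteins, a list written after the main results were seen, had a median of 0.56 in Total. A rise near that of the GABA and glycine receptors and the chaperones was thus not particular to them.

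Lists of habenula and thalamus markers, ion channels, transmitter receptors, astrocytes and microglia were also called higher in Total RNA after shock, whereas oligodendrocyte markers (median 0.11, adjusted p = 0.065) and OPC markers (median 0.46, 0.075) were not. Adjusted over the list alone, 2 of 18 lateral habenula markers rose, Gabra1 and Slc17a6 (median 0.50, adjusted p = 2.6e-05, estimated adjusted p = 0.098). So did 1 of 23 medial habenula markers, the nicotinic receptor subunit Chrnb4 (1.46 ± 0.26, median 0.46, adjusted p = 3.3e-05, estimated adjusted p = 0.098), and 1 of 18 thalamus markers, the axon guidance gene Ntng1 (0.84 ± 0.14, median 0.16, adjusted p = 0.012, estimated adjusted p = 0.27). Of 32 sodium, calcium and HCN channels 3 rose, Scn1a (1.1 ± 0.19), Hcn4 (1.43 ± 0.32) and Scn2a (0.80 ± 0.21), with a median of 0.38 (adjusted p = 2.7e-04, estimated adjusted p = 0.13). Of 25 glutamate receptors 1 rose, the NMDA receptor subunit Grin1 (1.72 ± 0.29, median 0.32, adjusted p = 2.1e-04, estimated adjusted p = 0.13), and of 33 synaptic vesicle and release genes 3 rose (median 0.09, adjusted p = 0.0067, estimated adjusted p = 0.18), Syp, Syt1 (0.72 ± 0.17) and Syt11 (0.73 ± 0.17). Called as lists with 0 members passing alone were the 45 voltage-gated potassium channels (median 0.34, adjusted p = 0.038, estimated adjusted p = 0.14), the 29 other potassium channels (median 0.65, 8.9e-04, estimated adjusted p = 0.13), the 32 monoamine, acetylcholine and opioid receptors (median 0.29, 0.0053, estimated adjusted p = 0.17), the 20 astrocyte markers (median 0.49, 8.4e-05, estimated adjusted p = 0.098) and the 20 microglia markers (median 0.59, 0.031, estimated adjusted p = 0.19). In these 5 lists 6, 7, 2, 6 and 3 members were higher and 2, 0, 0, 1 and 0 lower at an unadjusted p under 0.05 with edgeR, DESeq2 called 1, 0, 0, 0 and 1 higher, and voom called 0. Lower lists were the choroid plexus and ependymal markers (median -0.57, adjusted p = 0.015, estimated adjusted p = 0.38) and the postsynaptic scaffold genes (median -0.18, 0.017, estimated adjusted p = 0.38), with 4 and 2 members lower at an unadjusted p under 0.05, 0 by edgeR over the list alone or over all genes, 1 and 1 by DESeq2 and 0 by voom.

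Single libraries decided some of the list calls in Total RNA. Without Total control 1 the choroid plexus and ependymal markers (adjusted p = 0.55), the monoamine, acetylcholine and opioid receptors (0.16) and the postsynaptic scaffold genes (0.21) were no longer called. Without Total control 2 this held for the microglia markers (0.14) and the voltage-gated potassium channels (0.17), and without Total shock 1 for the choroid plexus and ependymal markers (0.069) and the voltage-gated potassium channels (0.069). Without Total shock 2 it held for the thalamus markers (0.44), the microglia markers (0.17), the voltage-gated potassium channels (0.088), the synaptic vesicle and release genes (0.053) and the postsynaptic scaffold genes (0.19). The activity-induced genes were not called, with a median of 0.18 (adjusted p = 0.12).

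Shock against control in the IP asked what stress changed in the captured fraction, the comparison closest to the series title. Mitochondrial RNAs rose most, and few other genes passed, among them Rtn1 and Syp. The mitochondrially encoded list was lower in IP than in Total in both stress states. For mt-Co1 the log2 values were -2.41 in control and -1.73 after shock, and it rose by 2.08 in Total as well. The rise of these RNAs in the IP is therefore not shown to be a change among captured mRNAs. The complex I subunit mt-Nd4 rose by 3.24 ± 0.27 (67.2 ± 1.49 to 635 ± 255 CPM, adjusted p = 0.0036). The others named by the rule were mt-Nd5 (2.93 ± 0.27, 0.0072), mt-Nd6 (2.79 ± 0.31, 0.016), mt-Co1 (2.76 ± 0.16, 2.5e-04), mt-Nd2 (2.72 ± 0.29, 0.015) and mt-Cytb (2.71 ± 0.35, 0.042). Rtn1 (chromosome 12, 72211752 to 72409054) went from 353 ± 9.562 to 900.1 ± 4.936 CPM (log2 1.35 ± 0.13, adjusted p = 0.0072), and Syp (chromosome X, 7638471 to 7653256) from 201.3 ± 0.3513 to 435.0 ± 31.04 CPM (1.11 ± 0.15, 0.043). In all, 15 genes were higher, 11 of them mitochondrial genes or their nuclear copies. The remaining calls, chosen after their values were seen, were the sodium pump subunit Atp1b2 (1.39 ± 0.18, adjusted p = 0.0458) and the proteoglycan Spock2 (1.19 ± 0.14, 0.0299). With the mitochondrial genes taken out before scaling, an alternative chosen after seeing the data, 1 gene passed, Rtn1. By edgeR 0 genes were lower. At an unadjusted p under 0.05 there were 1175 higher and 812 lower, where chance gives 989 in all, DESeq2 called 336 and 185, the likelihood-ratio test 205 and 88, and voom 4 and 0. Lower without passing were the transporter Abca4 (-3.86 ± 0.56, adjusted p = 0.066), the histone Hist1h2bc (-1.97 ± 0.33, 0.12) and Skil, a repressor in TGF-beta signalling (-1.29 ± 0.21, 0.12). Without IP control 1 or IP control 2 the count was 2, without either Total shock library 6, without either Total control library or IP shock 1 it was 9, and without IP shock 2 it was 19. The call of mt-Co1 held without any 1 library, and Rtn1, mt-Nd4 and mt-Nd5 lost theirs without IP control 1 (0.12 to 0.17) or IP control 2 (0.10 to 0.12). The calls of mt-Nd6, mt-Nd2 and mt-Cytb ended without either IP control or either Total shock library and some others (0.054 to 0.54), and that of Syp without any 1 of the 8 (0.055 to 0.54).

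Kcnb1 did not pass in the IP after shock. It stood at 191 ± 22.1 CPM in control and 317 ± 65.2 CPM after shock, with both shock libraries above both control libraries, a log2 difference of 0.73 ± 0.19 (unadjusted p = 0.0034, adjusted p = 0.30, and 0.076 adjusted over the list of voltage-gated potassium channels alone). DESeq2 gave an adjusted p of 0.038 for Kcnb1, the likelihood-ratio test 0.087 and voom 0.34, and over all alternatives it ran from 0.038 to 0.75. Without 1 library the value ran from 0.50 (IP shock 1) to 0.93 (IP shock 2). Gpr151 was at 4.14 ± 0.257 CPM in control and 15.7 ± 0.378 CPM after shock (log2 1.92 ± 0.38, adjusted p = 0.17) and Slc17a6 at 1.25 ± 0.20 (0.10). Both passed adjusted over the list of lateral habenula markers alone (0.0055 and 0.0026). The others were 1.04 ± 0.43 for Fos (0.47), 0.05 ± 0.25 for Egr1 (0.98), -0.26 ± 0.57 for Arc (0.94), 0.59 ± 1.3 for Npas4 (0.94), 0.72 ± 0.40 for Gfap (0.57), 0.45 ± 0.14 for Mbp (0.39) and -0.28 ± 0.22 for Rps6 (0.70).

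**Figure D2:**
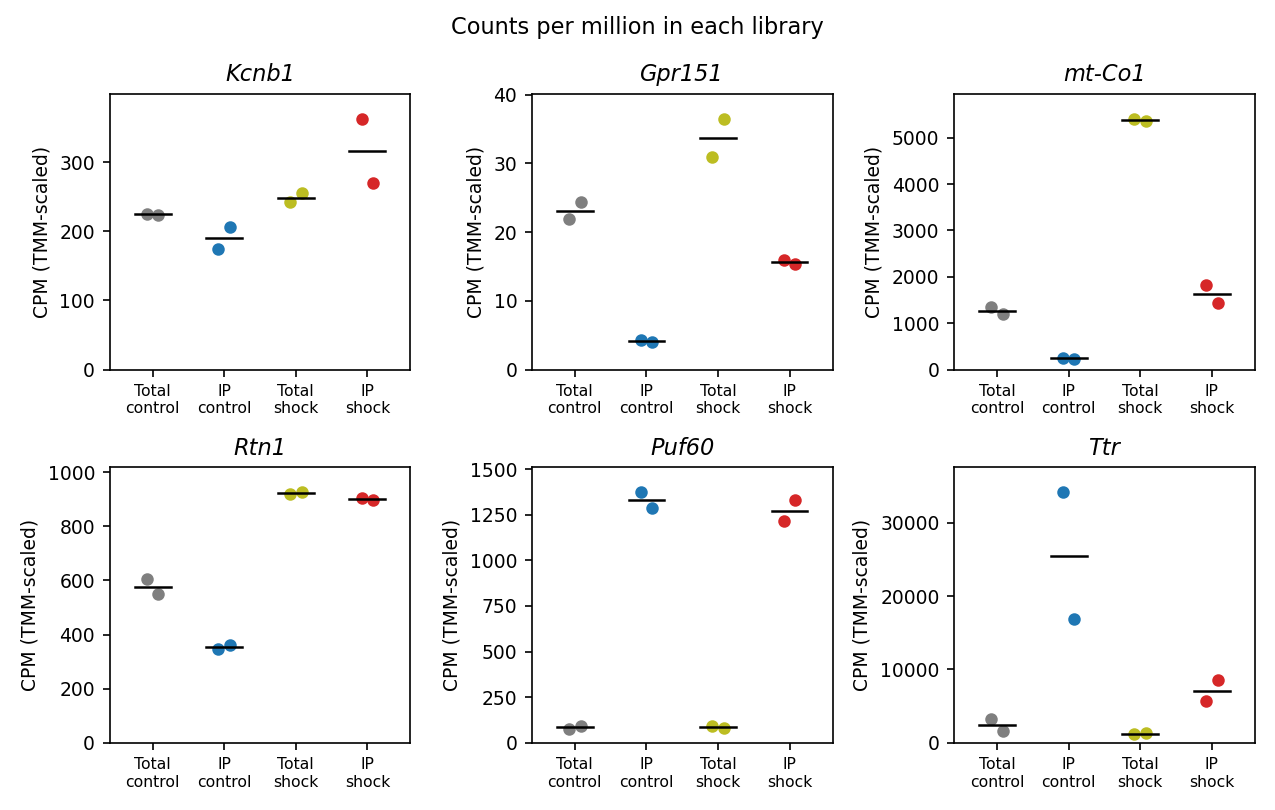
TMM-scaled CPM in each of the 8 libraries for Kcnb1, Gpr151, mt-Co1, Rtn1, Puf60 and Ttr, with points for libraries, bars for the mean of each group of 2, and every axis starting at 0. Kcnb1 has a mean of 317 in IP shock against 191 in IP control, and Puf60 differs between fractions and not between stress states, with means of 84.2 and 86.8 in Total against 1330 and 1270 in IP.

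Lists of glutamate receptors, GABA and glycine receptors and ion channels were higher in the IP after shock, whereas the 32 monoamine, acetylcholine and opioid receptors were not called (median 0.20, adjusted p = 0.32). With the preset correlation 16 lists were higher and 4 lower, and 0 with an estimated one. Of 25 glutamate receptors 23 had positive values and 9 rose adjusted over the list alone (median 0.87, adjusted p = 3.1e-08, estimated adjusted p = 0.089), among them Grin3a (1.25 ± 0.29) and the metabotropic receptor Grm5 (0.88 ± 0.25). Of 20 GABA and glycine receptors 17 had positive values and 8 rose (median 0.82, adjusted p = 6.5e-08, estimated adjusted p = 0.089), with the GABA-B receptor subunits Gabbr2 (1.25 ± 0.20) and Gabbr1 (0.88 ± 0.21). Of 32 sodium, calcium and HCN channels 8 rose (median 0.48, adjusted p = 2.7e-05, estimated adjusted p = 0.089), such as Scn8a (1.07 ± 0.24) and Cacna2d1 (1.25 ± 0.34). Of 29 other potassium channels 5 rose (median 0.50, adjusted p = 2.1e-04, estimated adjusted p = 0.089), including the calcium-activated Kcnn3 (1.05 ± 0.21) and the sodium-activated Kcnt1 (2.37 ± 0.63). Of 45 voltage-gated potassium channels 31 had positive values and 0 passed alone (median 0.42, adjusted p = 0.0010, estimated adjusted p = 0.089). The smallest p-values among them were those of Dpp10 (1.11 ± 0.24, 0.057 adjusted over the list alone), Kcnb1, Kcnc2 (0.72 ± 0.20, 0.084) and Kcnh2 (1.28 ± 0.38, 0.090). Over all genes 0 members of these 5 lists passed with edgeR or voom, against 12, 10, 9, 9 and 9 higher and 0, 0, 0, 0 and 1 lower at an unadjusted p under 0.05 in the order given, and 2, 5, 7, 5 and 3 called higher by DESeq2. The share of mitochondrial reads in the same libraries was 0.256% and 0.265% in control and 1.51% and 1.1% after shock, and that of choroid plexus and ependymal markers 3.69% and 1.92% in control and 0.650% and 0.974% after shock. Housekeeping mRNAs of secreted and membrane proteins, a list written after the main results were seen, had a median of 0.58 in IP. The channel lists lay below that value, and the lists of glutamate and of GABA and glycine receptors above it.

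Presynaptic, neuronal and habenula lists were higher in the IP after shock as well. Of 21 neuronal markers, 2 rose over all genes, Rtn1 and Syp, and 4 adjusted over the list alone (median 0.28, adjusted p = 1.6e-06, estimated adjusted p = 0.089). Of 33 synaptic vesicle and release genes, 1 rose over all genes, Syp, and 8 adjusted over the list alone (median 0.11, adjusted p = 2.8e-04, estimated adjusted p = 0.089), such as Sv2b (1.30 ± 0.19) and Syt1 (0.93 ± 0.17). Of 18 lateral habenula markers 4 rose adjusted over the list alone, Slc17a6, Gpr151, the secreted neuropeptide precursor Vgf (1.94 ± 0.56) and the protocadherin Pcdh10 (0.95 ± 0.29), with a median of 0.28 (adjusted p = 6.9e-04, estimated adjusted p = 0.089). Of 23 medial habenula markers 3 rose, led by the nicotinic receptor subunit Chrna3 (1.72 ± 0.31), with a median of 0.70 (adjusted p = 4.9e-04, estimated adjusted p = 0.089). Of 6 glutamatergic neuron genes 1 rose, Slc17a6 (median 0.73, adjusted p = 0.0031, estimated adjusted p = 0.16). Of 23 neuropeptides 20 had positive values and 0 passed alone (median 1.19, adjusted p = 0.0011, estimated adjusted p = 0.28). Of 16 glucocorticoid-induced genes 14 had positive values and 1 rose, Per1 (1.75 ± 0.27), which is also in the activity-induced list. The median was 0.84 (adjusted p = 3.3e-04, estimated adjusted p = 0.089). Among the last 5 lists 0 members passed over all genes with edgeR or voom, against 7, 9, 4, 6 and 5 higher at an unadjusted p under 0.05 and 3, 3, 1, 3 and 2 called higher by DESeq2. The glutamatergic call ended without IP shock 1 (adjusted p = 0.11).

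Glial and other lists moved in the IP in both directions after shock. Of 11 mitochondrially encoded mRNAs, 7 rose over all genes and 10 adjusted over the list alone (median 2.72, adjusted p = 2.4e-16, estimated adjusted p = 0.089). Of 20 astrocyte markers 3 rose adjusted over the list alone, Aqp4 (0.78 ± 0.20), Gja1, a gap junction protein (1.36 ± 0.38), and Slc1a2, a glutamate transporter (0.68 ± 0.20), with a median of 0.68 (adjusted p = 0.0037, estimated adjusted p = 0.089). Of 21 oligodendrocyte markers 1 rose, Plp1 (chromosome X, 136822671 to 136839733, 0.97 ± 0.13), with a median of 0.45 (adjusted p = 0.0048, estimated adjusted p = 0.28). The 31 secretory and ER chaperone genes had a median of 0.25 (adjusted p = 0.020, estimated adjusted p = 0.44). Of 18 choroid plexus and ependymal markers 10 fell adjusted over the list alone (median -1.18, adjusted p = 2.7e-10, estimated adjusted p = 0.089), including Clic6 (-2.07 ± 0.40), Kcne2 (-2.63 ± 0.53) and Ttr (-1.85 ± 0.39). Of 31 replication-dependent histones 1 fell, Hist1h2bc (median -0.66, adjusted p = 0.0011, estimated adjusted p = 0.15). The 76 nuclear-encoded oxidative phosphorylation genes (median -0.22, adjusted p = 1.9e-06, estimated adjusted p = 0.50) and the 86 cytosolic ribosomal proteins (median -0.17, 7.6e-04, estimated adjusted p = 0.53) were lower as lists. Over all genes 0 members of the astrocyte, oligodendrocyte, chaperone, choroid plexus, histone, oxidative phosphorylation and ribosomal lists passed with edgeR or voom. At an unadjusted p under 0.05 there were 5, 7, 6, 0, 0, 0 and 0 higher and 1, 1, 1, 11, 3, 7 and 3 lower in that order, and DESeq2 called 2, 1, 2, 0, 0, 0 and 0 higher and 0, 0, 1, 10, 2, 0 and 0 lower. Without IP shock 1 the oligodendrocyte markers (adjusted p = 0.054), the cytosolic ribosomal proteins (0.95) and the nuclear-encoded oxidative phosphorylation genes (0.99, with the direction turned) lost their calls. Without IP control 2 the oligodendrocyte markers (0.23), the cytosolic ribosomal proteins (0.18) and the secretory and ER chaperone genes (0.19) did, and the last also without IP shock 2 (0.84).

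The shock effect was compared between fractions. The 3 genes called in Total were among the 15 called in IP, where independent draws would share 0.00227, and all 15 had the same sign in Total. Both tests again use the same estimate of each gene's spread, so the calls are not independent. Across all genes, which are not independent replicates, Pearson's r of the log2 changes was 0.072, and 0.40 over the 5690 genes at a mean log2 CPM of at least 5. The direct test of the difference, IP over Total after shock against IP over Total in control, called 0 genes higher and 0 lower by edgeR, with a smallest adjusted p of 0.826. At an unadjusted p under 0.05 there were 656 higher and 518 lower, where chance gives 989 in all, DESeq2 called 29 and 16, the likelihood-ratio test 30 and 16, and voom 0 and 0. So the changes called in a single fraction were not shown to differ between fractions. The genes of smallest p, none of which passed, were mt-Nd4 at 1.65 ± 0.36, the phosphatase Ssh1 at 2.06 ± 0.48 and the cytokine receptor Csf2ra at 3.17 ± 0.78 upward. Downward they were Cfap65 at -4.14 ± 0.77, the lipid carrier Apoe at -1.13 ± 0.24 and Pon2 at -3.16 ± 0.68 (adjusted p = 0.83 for each of the genes named). Kcnb1 was at 0.58 ± 0.26 (unadjusted p = 0.053, adjusted p = 0.83), Gpr151 at 1.38 ± 0.51 (unadjusted p = 0.025), Gfap at 1.46 ± 0.57 (0.029), Slc17a6 at 0.46 ± 0.28 (0.14), Mbp at 0.41 ± 0.20 (0.074), Fos at -0.82 ± 0.60 (0.21), Egr1 at -0.36 ± 0.36 (0.34), Npas4 at -2.01 ± 1.9 (0.31), Arc at -0.06 ± 0.81 (0.95) and Rps6 at 0.00 ± 0.31 (0.99). Without Total control 2 the count of genes higher was 1.

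Among the lists, 1 was higher and 4 lower by the direct test with the preset correlation, and 0 with an estimated one. The mitochondrially encoded mRNAs rose more in IP than in Total (median 0.79, adjusted p = 0.0014, estimated adjusted p = 0.76), and 1 member passed adjusted over the list alone, mt-Nd4. Lower in IP relative to Total were the nuclear-encoded oxidative phosphorylation genes (median -0.33, adjusted p = 2e-07, estimated adjusted p = 0.77), the choroid plexus and ependymal markers (median -0.75, 0.012, estimated adjusted p = 0.76), the heat shock genes (median -0.21, 0.024, estimated adjusted p = 0.76) and the replication-dependent histones (median -0.94, 0.025, estimated adjusted p = 0.76). Among these 5 lists 0 members passed over all genes with edgeR or voom, against 6, 0, 0, 0 and 0 higher and 0, 4, 4, 0 and 2 lower at an unadjusted p under 0.05 in the order given, and DESeq2 called 1 higher in the first and 1 lower in the last. Each call ended without at least 1 library. The mitochondrially encoded mRNAs lost theirs without Total control 1 (adjusted p = 0.070), and the nuclear-encoded oxidative phosphorylation genes without IP shock 1 (0.37). The choroid plexus and ependymal markers lost theirs without IP control 1 (0.15), IP shock 1 (0.11), Total control 2 (0.18) or Total shock 2 (0.11). The heat shock genes lost theirs without Total control 1 (0.31), IP shock 1 (0.29), IP control 2 (0.14) or Total shock 2 (0.13), and the replication-dependent histones without Total shock 1 (0.28), IP shock 1 (0.13), Total control 2 (0.11) or IP control 2 (0.084).

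**Figure D3:**
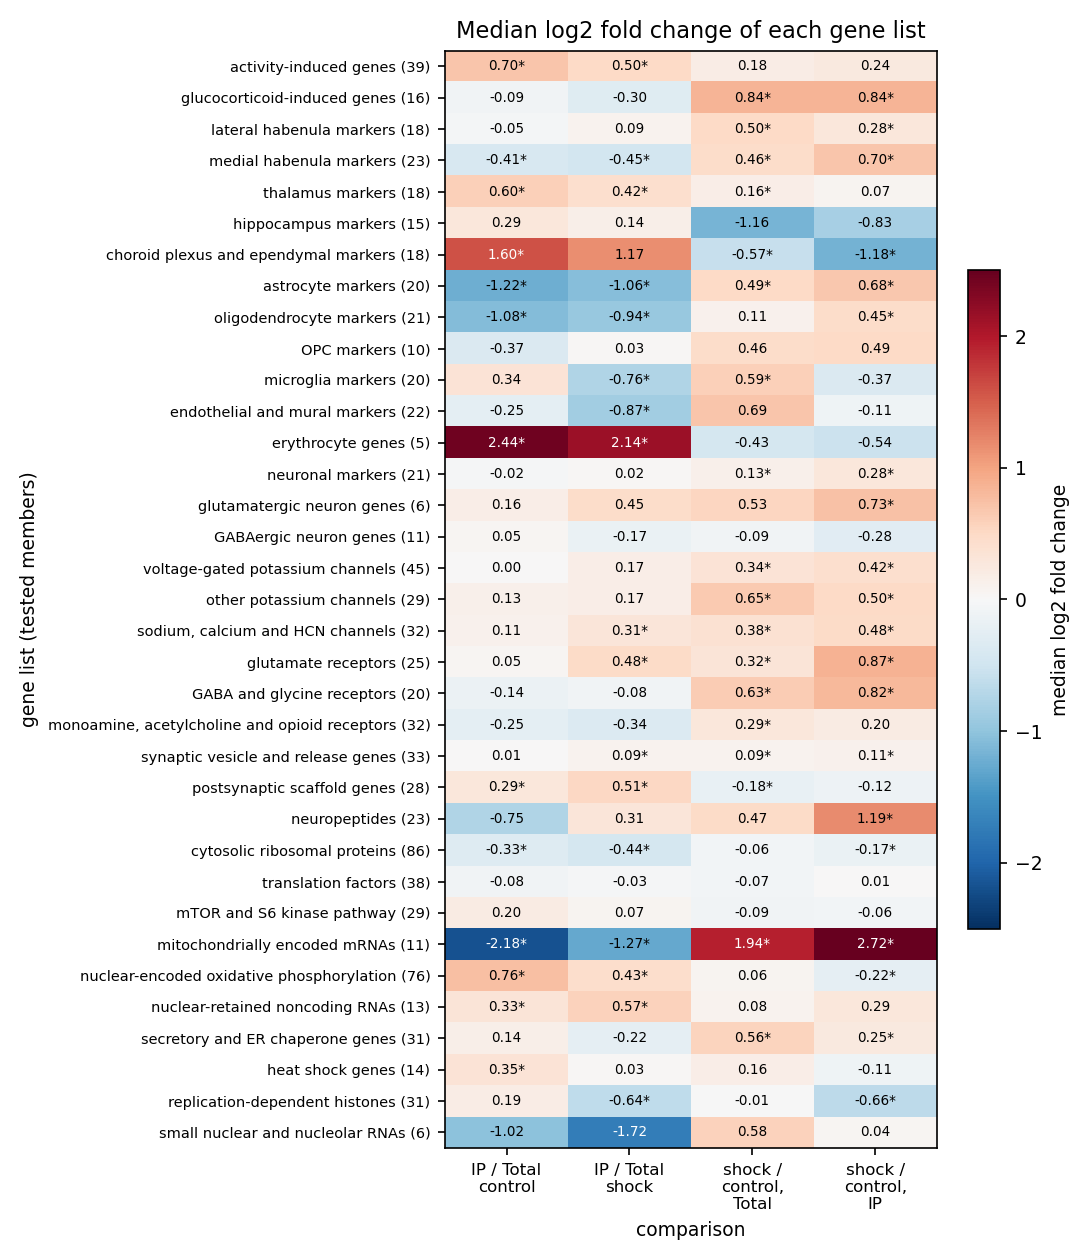
Median log2 fold change of the tested members of each of the 35 gene lists (number of members in parentheses) in the 4 pairwise comparisons, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The mitochondrially encoded mRNAs run from -2.18 and -1.27 for IP over Total to 1.94 and 2.72 for shock over control.

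A few lists were called in no comparison. The smallest adjusted p of the 15 hippocampus markers was 0.10, for shock against control in IP (median -0.83). That of the 10 OPC markers was 0.075, for shock against control in Total (median 0.46), and that of the 11 GABAergic neuron genes was 0.23, for shock against control in IP (median -0.28). The 38 translation factors had medians between -0.08 and 0.01 and adjusted p-values from 0.43 to 0.97. The 29 genes of the mTOR and S6 kinase pathway had medians between -0.09 and 0.20 and adjusted p-values from 0.43 to 0.97, and the 6 small nuclear and nucleolar RNAs had their smallest adjusted p, 0.16, for IP against Total after shock (median -1.72).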

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

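Tests of splicing proteins without charged domains, of charged repeats, of cytosolic neuronal markers and of membrane-bound RNA had predictions written before their values were seen, and all others were chosen after the result was seen. Even so, the list of charged splicing proteins was written after some of its members had been seen, and the housekeeping lists after the main results. These tests were therefore not planned before the data were examined. The rule that labels them was moved to bootstrap intervals (10000 draws of genes, 95%) after a first run. Genes across a list are not independent replicates, so the intervals describe genes and not animals.

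Mitochondrially encoded RNAs were higher after shock in Total and in IP. A larger share of cells rich in respiratory transcripts might do this, but the nuclear-encoded oxidative phosphorylation genes had a median log2 change of 0.06 in Total [0.02, 0.10]. More ribosomal RNA carried into the shock libraries might do so too, but 4 genes that collect nuclear ribosomal RNA reads had a median of 0.06 in Total (range -0.03 to 0.45). The nuclear-encoded values argue against the first. The 4 genes argue against the second only as far as they follow the ribosomal RNA carried over. Both tests were chosen after the result was seen. A change with stress itself, or in how much mitochondrial RNA each lysate released, stays open, as the labels give no day or batch of collection.

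mRNAs of splicing proteins with charged arginine-rich domains leaned higher in IP in both stress states. Of 51 tested, 36 were positive and 14 called higher in control, and 39 were positive and 12 called higher after shock. A rise of the whole splicing class could account for this. The other splicing proteins listed had a median of 0.16 in control [-0.05, 0.32], with 0 of 54 called, so as a set they did not share the rise. The highest of them was at 1.38, so the splicing factor Puf60, at 3.98, was not in that list. A list without such a gene cannot decide on the whole class. Nuclear RNA carried into the IP could add to the rise of the charged list. The nuclear-retained noncoding RNAs, at a median of 0.33 [0.12, 1.04], neither show nor exclude that. Not every RNA named in that list is strictly nuclear (Gas5 and Norad are not), so it measures nuclear RNA only in part. Capture that depends on the charged repeats or their RNA could too, and the medians differed by 0.25 in control [-0.10, 0.66] (permutation p = 0.14). That difference lay under the limit written beforehand for no such capture, while the interval rule brought in later leaves it undecided. After shock, which the prediction did not cover, the difference was 0.61 (permutation p = 0.00001, the smallest that 100000 resamples of genes taken as independent can give). The list was written after some of its members had been seen, so these p-values lend that explanation no support. A capture without antibody was not analysed here, so translation in active cells stays open as well.

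Several lists of receptors and channels, which are membrane proteins, and the secretory and ER chaperones were called higher after shock in both fractions with the preset correlation. Choroid plexus and ependymal markers, among them the secreted Ttr, went the other way, with a median of -1.18 in IP. Better recovery of membrane-bound RNA in the shock lysates could produce the rise, and would raise housekeeping mRNAs of secreted and membrane proteins too. These lay above those of cytosolic proteins by 0.52 in Total, the smaller of the fractions' differences [0.37, 0.73], as that explanation predicts. Of them 55 of 60 were positive in Total and 48 of 60 in IP, but 0 were called in either. The housekeeping lists were written after the main results were seen. A larger neuronal share in the shock dissections could contribute, and cytosolic neuronal markers had a median of 0.07 in Total [0, 0.25]. That median and the upper quartile (0.25) lay under the limits written beforehand for no larger share. The interval rule brought in later leaves it undecided. For the glial part, astrocyte markers had a median of 0.49 in Total [0.11, 0.85]. That list includes membrane proteins such as Aqp4, Gja1 and Slc1a2, which better recovery of membrane-bound RNA could raise whatever the cell shares. The astrocyte value therefore cannot decide on a larger neuronal share. An effect of shock on mRNAs of membrane and secreted proteins would give the same values and stays open.

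The change with shock in IP minus that in Total differed by camera's test with the preset correlation for 5 lists. Choroid plexus and ependymal markers differed by a median log2 of -0.75. Mitochondrially encoded mRNAs differed by 0.79. Nuclear-encoded oxidative phosphorylation genes differed by -0.33. Heat shock genes differed by -0.21. Replication-dependent histones differed by -0.94. With an estimated correlation none of the 5 passed (adjusted p 0.76 to 0.77). Among reads outside the main measurement, those assigned to no gene took 20.6% in IP shock 1 and 19.3% in IP shock 2, above the 16.2% to 18.8% of the control libraries.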

How the results depend on the processing

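The likelihood-ratio test and the fits without mitochondrial or choroid genes were chosen after the result was seen. None of the 82 named calls reversed under the settings run on them. Of 82 named calls, 81 kept their side of the threshold with RLE or upper quartile scaling, 80 with library totals, 82 without a filter, with the strict filter, with DESeq2 and with the likelihood-ratio test, 60 with voom and 42 with only the 4 libraries of the comparison. With mitochondrially encoded genes taken out 61 of 63 did. Without 1 library, whose lone mate is assumed to vary like the other groups, 38 to 76 did. For the shifts below the cause was not tested.

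In IP against Total in control the count of higher genes was 491 without a filter, 273 at 5 CPM in 2 libraries, 626 with DESeq2, 451 with the likelihood-ratio test and 19 to 164 without 1 library. The count of lower genes was 427, 223, 617 and 429 in the same order, 53 with voom, 39 with only the 4 libraries compared and 12 to 131 without 1 library. After shock the higher counts were 327, 167, 411 and 284, then 25 with only 4 libraries and 15 to 103 without 1 library. The lower counts were 200, 102, 331 and 215, then 8 and 6 to 33. The cause was not tested.

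In shock against control in Total the higher counts were 75, 7, 106 and 47, with 0 once mitochondrially encoded genes were taken out and 0 to 7 without 1 library. Lower counts were 66 without a filter, 55 with DESeq2, 27 with the likelihood-ratio test and 0 to 1 without 1 library. In IP the higher counts were 232, 45, 336 and 205, then 4 with voom, 2 with only 4 libraries, 1 without mitochondrially encoded genes and 2 to 19 without 1 library. The lower counts were 126, 9, 185 and 88. For the shock effect on IP over Total they were 53 higher and 31 lower without a filter, 29 and 16 with DESeq2, 30 and 16 with the likelihood-ratio test, and 0 to 1 higher without 1 library. The cause was not tested.

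Called lists numbered 0 in all 5 comparisons with an estimated correlation. Without 1 library they numbered 11 to 13, 11 to 18, 13 to 21, 17 to 22 and 1 to 13 in the order of the comparisons. The adjusted p of nuclear-encoded oxidative phosphorylation in IP ran from 6.6e-26 to 0.99, with the direction turned without IP shock 1. Pearson's r of IP enrichment between the stress states was 0.082 without a filter, 0.336 with the strict filter and 0.104 to 0.169 without 1 library. That of the shock effect between fractions was 0.041, 0.160 and 0.035 to 0.094. The cause was not tested.

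Genes that did not pass changed sign in places. Mbp in Total was -0.10 with library totals and -0.03 to 0.09 without 1 library. Egr1 in IP was -0.04 with voom and -0.39 to 0.39 without 1 library. Rps6 in the shock effect on IP over Total was 0.01 with RLE, upper quartile and DESeq2, 0.12 with library totals, 0.03 with voom and -0.20 to 0.18 without 1 library. Without 1 library Arc ran from -0.36 to 1.43 in IP against Total after shock, from -0.94 to 0.29 with shock in Total, from -1.3 to 0.35 with shock in IP and from -1.1 to 0.68 in the shock effect on IP over Total, where library totals gave 0.04. Npas4 ran from -0.38 to 3.67, from -0.54 to 5.22, from -0.05 to 1.33 and from -4.63 to 1.13. The cause was not tested.

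With a replicate block the counts were 102 higher and 72 lower for IP against Total in control, 76 and 35 after shock, 3 and 0 for shock in Total, 12 and 0 in IP and 0 and 0 for the shock effect on IP over Total. With the replicate block within each stress state 52 genes were lower in control. The replicate block kept 76 of the 82 named calls, and the replicate block within each stress state 53 of 70. Deviations of libraries with the same replicate number correlated at -0.007 to 0.024 across all tested genes, which gave no sign of pairing. Genes of low count weaken such correlations, so pairing is not excluded.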

Other observations

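The housekeeping lists compared here were written after the main results were seen. Housekeeping mRNAs of secreted and membrane proteins had a median log2 change with shock of 0.56 in Total, where 55 of 60 were positive, and 0.58 in IP, where 48 of 60 were. Those of cytosolic proteins had 0.04 in Total (49 of 88 positive) and -0.09 in IP (32 of 88). By edgeR 0 members of these lists passed in either fraction. The difference of medians was 0.52 in Total and 0.68 in IP (permutation p = 0.00001 each, the smallest that 100000 resamples can give), and 0.12 for the change in IP minus that in Total (p = 0.10). The permutation treats genes that vary together as independent. With an estimated correlation camera gave the secreted and membrane list an unadjusted p of 0.016 in Total and 0.040 in IP. The difference of medians ran from 0.48 to 0.61 in Total and from 0.62 to 0.76 in IP without 1 library. Between the libraries of a group that difference was -0.05 in Total control, -0.14 in IP control, 0.05 in Total shock and 0.08 in IP shock.

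A few genes were abundant in a single library. Erp29 stood at 12100 CPM in Total control 1 and 38.1 in Total control 2, Preb at 1190 and 54.3 in the same libraries, and Ext2 at 251 CPM in IP shock 2 and 11.4 in IP shock 1.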
